A study of Chlorocebus aethiops with 12 samples.

How the data were processed

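Total RNA of 12 COS-1 samples was labelled with Cy3 and hybridised to Agilent whole human genome arrays of the 4x44 format, with 1 sample per array, per the labels' protocols. The probes are human and the RNA is from the African green monkey, so a mismatch can lower a probe's signal and each probe was compared only with itself between groups. The labels give 3 replicates per group and do not say whether these were separate cultures, so p-values measure the spread between these arrays, which may be technical.

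The deposited spot intensity is the processed green signal of Agilent Feature Extraction version 12, background-subtracted and detrended within each array and not normalized between arrays, per the file headers. Other deposited columns used were the spot flags (well above background, saturated, outlier) and the median signal and background intensity, per the file headers. The values of the series table were set against the scanner files spot by spot, and 0 differed, so using them changed nothing. Of 45015 spots per array, 1639 control spots were left out. The remaining 43376 held 41000 distinct probes, 264 of them with 10 spots each.

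Groups were taken from the sample titles and descriptions. Another label lists a single construct for each mutant, the tagged CCRP for Y30F samples and the tagged receptor for Y30E samples, while the descriptions list both constructs for every sample, and the descriptions were followed. Slides were identified from the file headers and numbered 1 to 3, with 4 arrays each. Slide 1 held the 3 Y30F-DMSO arrays and Y30F-DEX replicate 1, slide 2 held Y30F-DEX replicates 2 and 3 and Y30E-DMSO replicates 1 and 2, and slide 3 held Y30E-DMSO replicate 3 and the 3 Y30E-DEX arrays.

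Each array's log2 signal was reduced by its 75th percentile over non-control spots (signals of 706 to 876 at that percentile), with 89 to 154 outlier spots per array left out. Spots of a probe were averaged. A probe was kept where at least 0.5 of its spots were well above background on all arrays of at least 1 group, which held for 25570 probes. For each record ID the probe with the highest mean over the 12 arrays was used, which gave 20037 features. Of 4393 records with more than 1 such probe, the other probes of changed records were checked for direction.

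The main test was limma 3.58.1 (lmFit and eBayes, R 4.3.3) on 4 group means over all 12 arrays (8 residual degrees of freedom), with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. A feature past the threshold is described as changed, higher or lower. There were 5 comparisons: the dexamethasone effect in each mutant, the difference of these effects (Y30E effect minus Y30F effect), and Y30E minus Y30F under each treatment. Errors are limma's standard errors or SDs over 3 arrays. Where a probe was not well above background on any array of a group, the fold is a lower bound for the main processing alone. That bound leaves out offsets between slides. It sets the brighter group's mean against the dimmer group's mean of, per array, the higher of that array's lowest signal well above background and the probe's own. Shared calls of the mutants were set against the number expected for independent lists. These 2 effects use different arrays.

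The scripts' statistics were tested on simulated data made from the real means and spreads of 20037 features, with 200 features changed and no slide offsets. For the effect in Y30F, changes of 0.5, 1 and 2 (log2) were recovered in 61.2%, 89.6% and 97.0% of cases, with 6.78% false calls. For the difference of the effects the shares were 43.3%, 85.1% and 90.9%, with 3.95% false calls.

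These choices, the alternatives and the rule for named features were fixed before the data were examined, apart from 2 alternatives. Those 2 were leaving out slide 2 and testing the brightest 6679 features alone. The rule was changed when applied, as given below, and the Fisher's exact tests of record types were not in the plan. The alternatives were quantile normalization, median centring, normexp background correction (offset 50) with the 75th percentile or with quantile normalization, the series table, no filter or a filter on all 12 arrays, all probes, slide as a fixed or random block, arrays of 1 slide, the replicate number as a block, the compared groups alone, other priors, other thresholds, array weights, and leaving out each array. The normexp correction used the median signal, since the mean signal named in the plan is not among the columns used here. Its offset of 50 is added to every corrected signal, so it shrinks the log2 changes of dim features whatever their true fold. The statmod 1.5.0 package served the random block.

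The rule for named features asked for gene names, up to 12 per direction with arrays that do not overlap between groups. It left out features known only by a record or probe ID. Scanner files gave record IDs with no names, so, against that part of the rule, its order was applied to IDs and stopped at 2 per direction. For the difference of the effects, where none passed, the smallest p-values were taken, 2 per direction where the rule asked for 3. The 3 opposed features are the exception, named after their values were seen. For the same reason 16 gene lists fixed beforehand (glucocorticoid-induced genes and metallothioneins among them) and the levels of the transfected receptor and CCRP transcripts were not analysed here.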

Results

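Transcript levels were measured in COS-1 cells, an African green monkey kidney line, after transient transfection of mouse CCRP (a co-chaperone of nuclear receptors) with V5 tag and human glucocorticoid receptor (GR) with FLAG tag. The receptor carried phenylalanine (Y30F) or glutamate (Y30E) in place of a tyrosine in its N-terminal part. From 40 h after transfection the cells received 100 nM dexamethasone, a synthetic glucocorticoid, or 0.1% DMSO, the vehicle, for 6 h. Each of the 4 groups had 3 arrays, 12 in all, hybridised to a human whole-genome 1-colour array. The series title sets a receptor whose N- and C-terminal parts interact against one in which they do not, and the labels used here do not say which mutant is which. Between 60.5% and 67.0% of spots per array were well above background (26256 to 29067 of 43376 non-control spots), and no such spot was saturated. After filtering, 20037 features were tested, where a feature is 1 transcript record, or 1 probe where the files give no record. The number of arrays limits the precision, with a median standard error of 0.08 (log2) for the effect of dexamethasone in either mutant. The files do not pair record IDs with gene names, so genes are not named, and at most 2 IDs are given per direction in a comparison.

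The first question was what dexamethasone changed in cells with the Y30F receptor. After 6 h, 365 features had changed, 287 higher and 78 lower, and 46 of the higher ones but 2 of the lower ones had changed at least 2-fold. The transcript NM_016084 rose 14.1-fold, by 3.82 ± 0.09 (log2, SE, n = 3 against 3), from a mean signal of 434 in Y30F-DMSO to 5919 in Y30F-DEX. NM_000547 was not well above background on any Y30F-DMSO array and was on 3 of 3 Y30F-DEX arrays, at least 2.05-fold higher in the main processing. With normexp its log2 change in Y30F was 0.70, smaller than this bound, and it still passed. The normexp offset of 50 alone shrinks changes of such dim features, so this does not test the bound. NM_018933 fell to a signal of 1081 from 4376, a log2 change of -1.97 ± 0.15, and A_23_P300563 fell to 8742 from 26737, a change of -1.58 ± 0.08. The limma adjusted p-values of the 4 features were 1.74e-08, 1.14e-05, 1.02e-04 and 5.12e-06 in that order. Among other probes for the changed transcripts, 101 of 110 (91.8%) moved in the same direction and 0 had changed in the opposite one. The median change among the 287 higher features was 0.54 (log2), and among the 78 lower ones it was -0.43. Annotated protein-coding RefSeq records (NM) made up 81.9% of the changed features and 71.7% of those tested. Fisher's exact test (2-sided) gave an adjusted p of 4.06e-05 over 14 tests. That test treats features as independent although they share arrays, and it takes no account of signal level.

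The arrays came on 3 slides, and the Y30F-DEX group was divided between slide 1, which also held all Y30F-DMSO arrays, and slide 2. Within Y30F-DEX and within Y30E-DMSO, slide 2 was set against the other slide. In both groups 215 features were more than 1 (log2) higher on slide 2, and 5 were that much lower. The median shift was 0.02 and 0.01. A higher slide 2 raises the apparent Y30F effect, so the 46 rises of at least 2-fold against 2 falls may partly reflect it. The slide block, slide 1 alone and leaving out slide 2 therefore give the same effect sizes, from the arrays of slide 1. With slide as a block 120 features had changed, 95 higher and 25 lower, and 95 of the 120 were among the 365. Within slide 1 (a single Y30F-DEX array) all 365 kept their direction, though that array also enters the 365, and 6 features, all higher, passed the test there. The count was 137 with the compared groups alone and 1252 with array weights. Those weights were 0.54 for Y30F-DEX replicate 1, on slide 1, and 0.56 and 2.88 for replicates 2 and 3, on slide 2. Without Y30F-DEX replicate 1 the count was 1367, without replicate 2 it was 237, and without replicate 3 it was 207. With slide 2 left out, an alternative chosen after the data were seen, it was 39.

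The same comparison in cells with the Y30E receptor gave 423 changed features, 299 higher and 124 lower, with 31 and 16 of these at least 2-fold changed. NM_016084 again rose, 15.7-fold (3.97 ± 0.09 on the log2 scale, n = 3 against 3, limma adjusted p = 1.17e-08), from a mean signal of 402 to 6401. NM_000547 was again not well above background under DMSO and was at least 2.0-fold higher with dexamethasone in the main processing (limma adjusted p = 7.63e-06). With normexp its log2 change in Y30E was 0.54, smaller than this bound, and it still passed. The lowest log2 fold changes were those of dim features. NM_017534 and THC2667587 were well above background on 3 of 3 Y30E-DMSO arrays and on no Y30E-DEX array. In the main processing they were at least 2.48-fold and 3.32-fold lower (limma adjusted p = 0.0277 and 0.0305). With normexp the log2 changes were -0.73 and -0.89, smaller than these bounds. The normexp offset shrinks these changes, and that of NM_000547, whatever their true size. THC2667587 had signals of 88.4 and 86.1 on the slide 2 Y30E-DMSO arrays and 38.9 on the slide 3 one, so its bound includes any offset between slides. The difference for THC2667587 did not pass the test with slide as a block (adjusted p = 0.239), and over all its alternatives it fell below the threshold in 13 of 29. That for NM_017534 passed narrowly with the block (adjusted p = 0.0474) and fell below the threshold in 9 of 29 alternatives. Other probes for the changed transcripts moved the same way in 114 of 127 cases (89.8%). NM records were 83.2% of the changed features (Fisher's exact test, 2-sided, adjusted p = 4.14e-07, with the same limits).

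Slide 3 held all Y30E-DEX arrays and 1 Y30E-DMSO array, and the other Y30E-DMSO arrays were on slide 2. The upward shift of features on slide 2 lowers the apparent Y30E effect, so the falls of at least 2-fold may partly reflect it. The slide block, slide 3 alone and leaving out slide 2 again give the same effect sizes. When slide was a block, 182 features had changed, 102 higher and 80 lower, and 118 of the 182 were among the 423. Within slide 3 all 423 kept their direction, with the same reuse of arrays, and 47 features passed the test, 22 higher and 25 lower, with a single DMSO array in that test. Array weights gave 1937, 1071 higher and 866 lower. Y30E-DMSO replicates 1 and 2, on slide 2, had weights of 2.12 and 1.23, and replicate 3, on slide 3, had 0.57. The count was 184 without Y30E-DMSO replicate 1 and 204 without its replicate 2. Without Y30E-DEX replicates 1, 2 or 3 it was 228, 255 or 243, and without slide 2 it was 71.

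**Figure D1:**
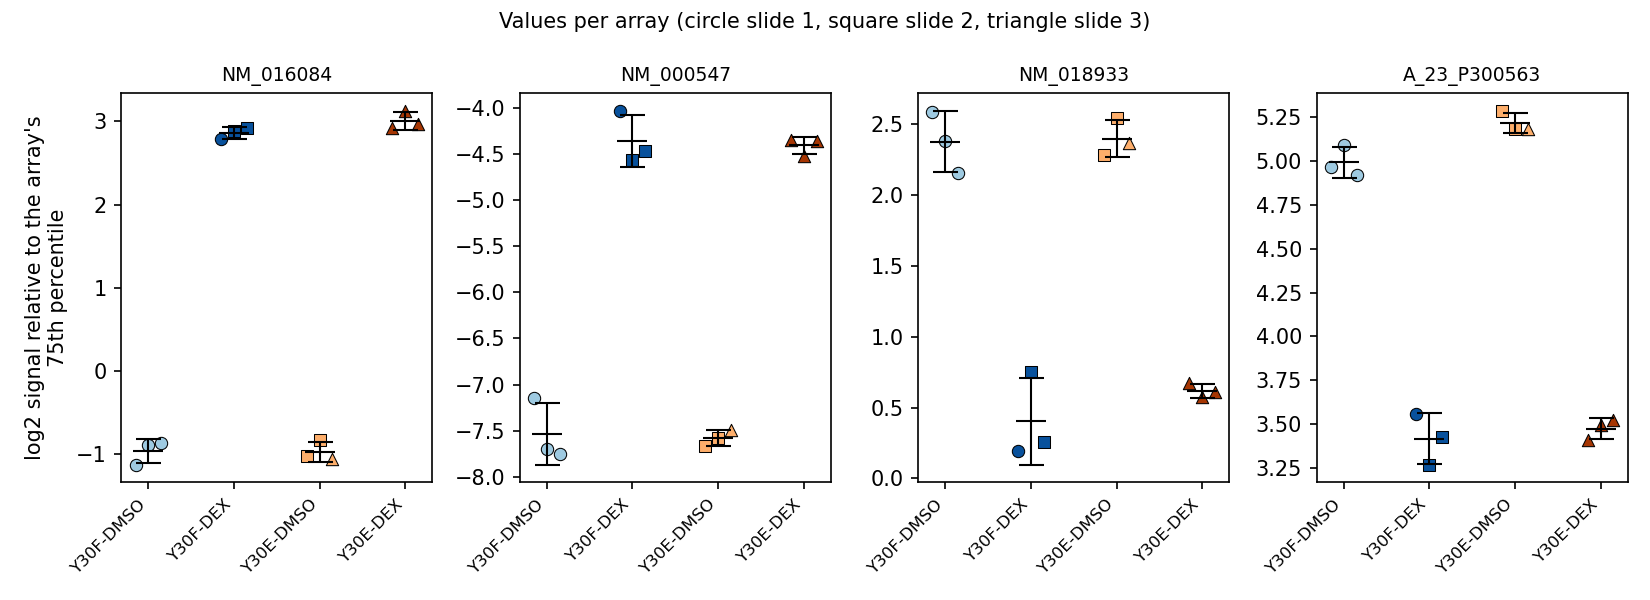
Normalized log2 signal of 4 transcripts on each of the 12 arrays, by group, with symbols for the slide, and the mean and SD of 3 arrays in black. NM_016084 and NM_000547 are higher, and NM_018933 and A_23_P300563 lower, with dexamethasone in both mutants, on every array.

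The features that dexamethasone changed in the 2 mutants overlapped. Of the changed features, 240 had changed in both, 186 higher in both and 51 lower in both. Independent lists of these lengths would share 4.28 and 0.483. The 2 lists are not fully independent, since both effects use 1 estimate of each feature's spread. Among the 240, 128 changed more strongly in Y30E. NM_018933 and A_23_P300563, which fell in Y30F cells, changed in Y30E cells by -1.78 ± 0.15 and -1.74 ± 0.08 (log2, SE, n = 3 against 3). Features that passed the test in 1 mutant alone moved the same way in the other in 96 of 125 cases for Y30F and in 149 of 183 for Y30E. With slide as a block, 72 features had changed in both mutants, 56 higher and 16 lower, with none opposed. A set of 66 features had changed in both mutants with and without the block, 52 higher and 14 lower. Without slide 2, 22 had changed in both. Without Y30E-DMSO replicate 1, 154 had.

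Across all 20037 features, which are not independent replicates, the Pearson correlation of the 2 effects was negative, -0.204, and with slide as a block it was positive, 0.307. Among the 19489 features that passed in neither mutant r was -0.406, and among the 19807 such features in the fit with the block it was 0.239. It depended on signal: with features ranked by mean signal, r was -0.320 in the dimmest 6679, 0.282 in the middle 6679 and 0.648 in the brightest 6679. Of the brightest, 91 features had changed in Y30F and 112 in Y30E, 76 of them in both, and 98.4% of those changed in either mutant moved the same way. Among the dimmest, 126 had changed in Y30F and 130 in Y30E, 56 in both, and 73.0% of those changed in either moved the same way, against 95.5% in the middle set. The 3 features that had changed in opposite directions were all among the dimmest 6679, higher in Y30F and lower in Y30E (NM_014943, NM_138969 and THC2725153, named here after their values were seen). None of the 3 had a difference of the effects past the threshold in the main fit. With slide as a block their Y30F and Y30E effects were 0.66 and -0.54, 0.35 and -0.53, and 1.02 and -0.50. For THC2725153 they were 1.31 and -1.12 without the block. The upward shift of features on slide 2 goes the same way.

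**Figure D2:**
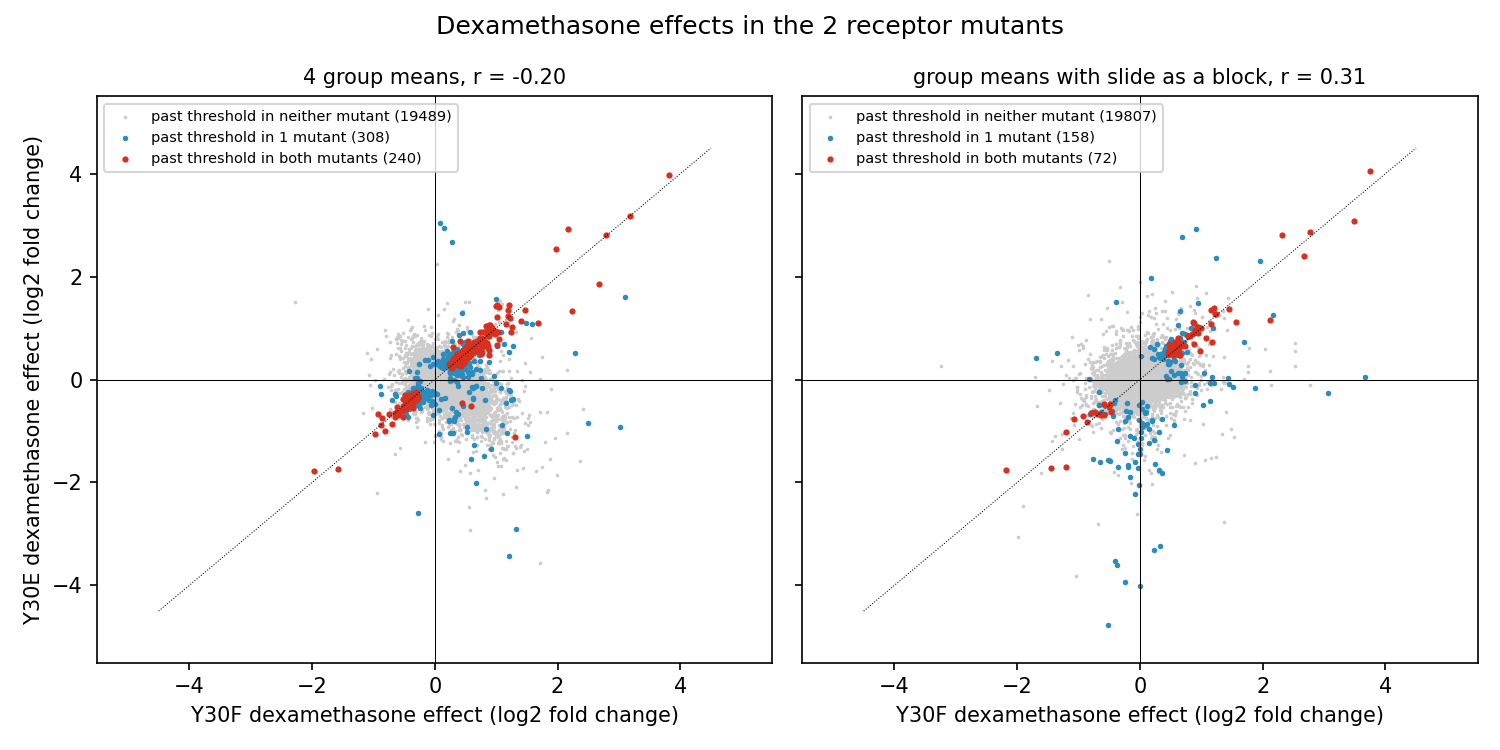
Dexamethasone effect in Y30E cells against that in Y30F cells (log2 fold change, 1 point per feature), from group means alone (left) and with slide as a block (right). The 240 and 72 features changed in both mutants lie along the diagonal, with 3 and 0 opposed. Over all features r was -0.204 on the left and 0.307 on the right.

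Whether the mutants differ in their response to dexamethasone was tested directly, as the Y30E effect minus the Y30F effect. No feature passed (limma, 0 of 20037, smallest adjusted p = 0.0599), while 2255 had an unadjusted p under 0.05, where 1002 would by chance. With slide as a block that number was 835, so the excess did not appear there. Each blocked effect rests on a single Y30F-DEX or Y30E-DMSO array, so real differences could also be missed there. For NM_016084 the difference was 0.15 on the log2 scale, with a 95% confidence interval from -0.13 to 0.43. Among the 240 features changed in both mutants, the median size of the difference was 0.07 (log2), and the 95% interval lay within 1.5-fold either way for 214 and within 2-fold for 232. For 15 of the 240 the interval excluded 0, and 4 had a difference past the threshold when adjusted over this set alone. Of the 548 features changed in either mutant, 135 intervals excluded 0 and 89 passed when adjusted over that set alone. Both sets were chosen on these same arrays, so these counts are not independent evidence, and the intervals leave out offsets between slides. Below the threshold, the smallest p-values were those of A_24_P935114 and NM_017831 (limma adjusted p = 0.0599 and 0.0720), both with a lower effect in Y30E. A_24_P935114 was not well above background on any Y30F-DMSO or Y30E-DEX array, so no size is given. For NM_017831 the difference was -0.97 ± 0.12 (log2, SE). The differences with the smallest p-values among those above 0 were NM_018289 and NM_013280, at 0.57 ± 0.09 and 0.58 ± 0.09 (limma adjusted p = 0.110 and 0.112). All 3 sizes depended on the processing, and the normexp offset alone shrinks those of such dim features. They were -0.34, 0.19 and 0.022 with normexp, and -0.61, 0.81 and 0.97 with quantile normalization. With slide as a block 18 features passed, 17 of them with a lower effect in Y30E, and with array weights 1641 did. The weights were highest on slide 2 in both divided groups, so the 1641 cannot be told apart from an offset between slides. Without slide 2 the count was 3, without Y30F-DEX replicate 1 it was 1130, without Y30E-DMSO replicate 3 it was 125, and without Y30E-DEX replicate 3 it was 1.

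The mutants were also compared under the same treatment. Under DMSO 2 features differed, both higher in Y30E and neither well above background on any Y30F-DMSO array. In the main processing NM_001039396 was at least 2.59-fold higher and NM_005282 at least 1.62-fold higher (limma, adjusted p = 0.0140 for both, n = 3 against 3). With normexp the log2 differences were 0.65 and 0.32, smaller than these bounds, and neither passed (limma adjusted p = 0.0851 and 0.109). The normexp offset shrinks differences of such dim features whatever their true size. NM_001039396 kept its call in the fit with the slide block (adjusted p = 0.0128) and NM_005282 did not (adjusted p = 0.456). No slide held both DMSO groups, so there is no within-slide value. The count was 0 without any 1 of Y30F-DMSO replicates 1 and 3 or Y30E-DMSO replicates 1 and 2. It was 11 without Y30F-DMSO replicate 2, 598 without Y30F-DEX replicate 1, 8 without Y30F-DEX replicate 2, 27 without Y30E-DMSO replicate 3 and 67 without slide 2. With the compared groups alone 165 features differed, 164 of them higher, and with array weights 924 did. Slide 2 held Y30E-DMSO replicates 1 and 2, and its large shifts, mostly upward, go the same way. These counts and the 598 therefore cannot be told apart from an offset between slides. None did with quantile normalization, the replicate block, the trend and robust prior or no moderation.

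Under dexamethasone 3 features differed. NM_198281 was well above background on the 3 Y30E-DEX arrays and on no array of the other groups, at least 1.55-fold higher than in Y30F-DEX. M13930 was 0.47 ± 0.06 (log2) higher. A_24_P935114 was at least 1.40-fold lower in Y30E-DEX, where it was not well above background (limma, adjusted p = 0.0459 for all 3, n = 3 against 3). With normexp the log2 differences of NM_198281 and A_24_P935114 were 0.48 and -0.27, smaller than these bounds, and the count was 0. The offset shrinks these 2 differences as well. None of the 3 passed with slide as a block (adjusted p = 0.437, 0.485 and 0.176), and 19 others did. No slide held both dexamethasone groups, and the count was 0 without any 1 of the 3 Y30F-DMSO arrays, Y30F-DEX replicate 2 or 3, or Y30E-DMSO replicate 2. It was 1 without Y30E-DEX replicate 1, 65 without Y30F-DEX replicate 1 and 66 without Y30E-DMSO replicate 3. Array weights gave 1216, and none differed with the compared groups alone, the replicate block, the trend and robust prior or no moderation. Without the slide block, counts here cannot be told apart from an offset between slides either.

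The arrays differed mainly along axes on which slide and group overlap. The first principal component held 35.8% of the variance, 98.2% of it between slides and 53.9% between groups, and set the 4 arrays of slide 2 apart. The second held 17.3%, of which 83.6% lay between slides and 91.1% between groups. Replicates on 1 slide differed with an SD of 0.202 to 0.276 (log2) over features in 8 pairs, and replicates on different slides with an SD of 0.313 to 0.398 in 4 pairs. In a fit of group and slide together, 1096 features (5.47%) differed between slides.

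**Figure D3:**
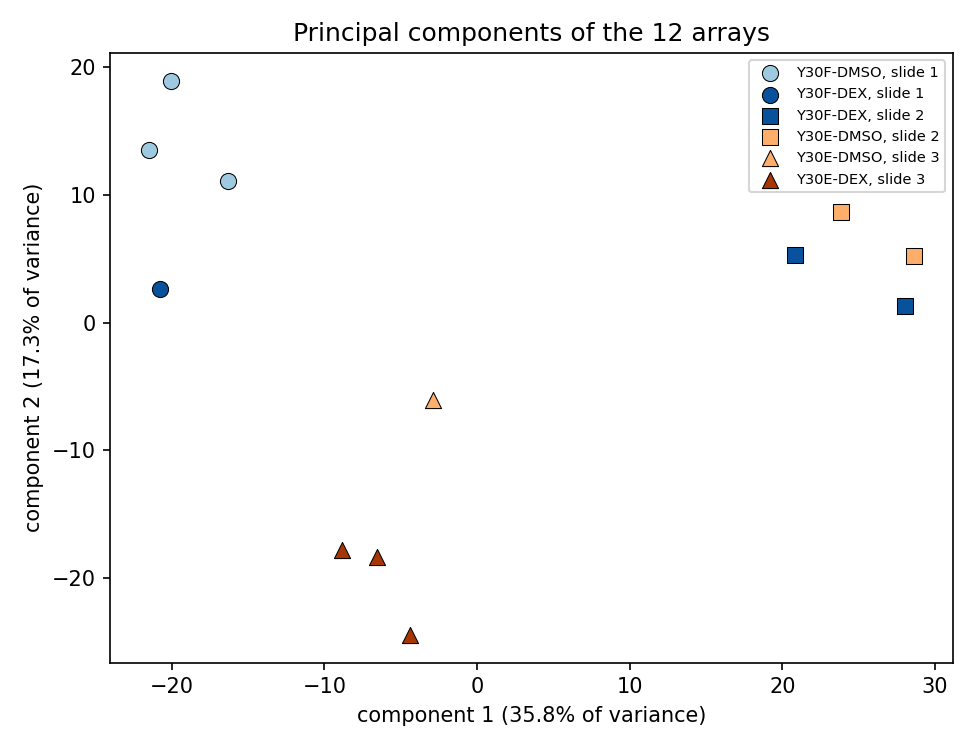
The 12 arrays on the first and second principal components of the normalized log2 values, with colours for the group and symbols for the slide. The 4 arrays of slide 2, from Y30F-DEX and Y30E-DMSO, lie to the right on component 1, which holds 35.8% of the variance.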

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

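Leaving out slide 2 and testing the brightest 6679 features alone were chosen after the data were seen. The fall of calls under the slide block and within slides goes with fewer arrays behind each effect. For the 2 effects and their difference, the block, the fits within slides and leaving out slide 2 give the same estimates. They are 1 reading, and their shared r of 0.307 counts once. The features picked by the rule, as applied to IDs, kept their sign in each alternative run on them (369 on the same side of the threshold, 109 weaker, 12 stronger). The 369 include differences of the effects that had not passed in the main fit, and the series table, whose values are identical. Calls between mutants were often lost: M13930 in 22 of 29 alternatives, A_24_P935114 in 20 of 28 and NM_198281 in 18 of 28. NM_005282 lost its call in 13 of 28 and NM_001039396 in 11 of 28. The all-probes fit and the 3 opposed features were not part of this tally. Sizes moved. The log2 difference of the effects was -0.34 for NM_017831, 0.19 for NM_018289 and 0.022 for NM_013280 with normexp. It was -0.61, 0.81 and 0.97 with quantile normalization. Every feature named with a lower bound had a normexp change smaller than that bound, as given above. The normexp offset of 50 forces such shrinkage in dim features, so this is no evidence on their size. The brighter NM_016084 went from 3.82 to 3.64 in Y30F. With slide as a fixed block the counts were 120 (Y30F effect), 182 (Y30E effect), 18 (difference of the effects), 19 (mutants under dexamethasone) and 72 (both mutants), and the correlation of the effects reversed to 0.307. Slide 1 alone gave 6 for Y30F and slide 3 alone 47 for Y30E. Without slide 2 the counts were 39, 71, 3, 67 (mutants under DMSO) and 22 (both mutants), and r reversed to 0.307. The brightest 6679 features gave 127 and 167 (fewer features tested), 98 in both, 0 and 0 between mutants, and r reversed to 0.648. For the causes of what follows no test was run. With the replicate number as a block the effects gave 272 and 308 features, the difference of the effects 1 and the mutant comparisons 0 and 0. Dexamethasone and DMSO arrays of the same number and mutant did not deviate together (r from -0.0588 to 0.0109 in 6 pairs). Over all 18 pairs of the same number r ran from -0.432 to 0.271, above 0.1 in 2. Array weights gave 1252 and 1937 for the effects, 1641 for their difference, and 924 and 1216 between mutants. In Y30F-DEX and Y30E-DMSO the weights were highest on slide 2, so these counts cannot be told apart from an offset between slides. The compared groups alone gave 137 for Y30F, 165 under DMSO and 0 under dexamethasone. An adjusted p under 0.01 gave 184, 172, 0 and 0, and a 1.5-fold minimum 146 and 137. No filter gave 259 for Y30E, 4 under DMSO and 1 under dexamethasone. Between mutants, in the order DMSO and dexamethasone, normexp gave 1 and 0, and that 1 was neither feature named under DMSO. In the same order the filter on all 12 arrays, the trend and robust prior and no moderation each gave 0 and 0. Quantile normalization gave 0 under DMSO, normexp with quantile 0 and 6, and all probes and the random block 0 each under dexamethasone. The correlation was -0.179 with quantile normalization, -0.0208 with normexp, -0.268 with no filter and -0.0738 with the filter on all 12 arrays. Quantile normalization moved the Y30F split from 287 higher and 78 lower to 217 and 113. Leaving out 1 array at a time gave 207 to 1367 for Y30F and 184 to 596 for Y30E. It gave 0 to 1130 for their difference, 0 to 598 under DMSO, 0 to 66 under dexamethasone, 154 to 323 in both mutants, and r from -0.334 to -0.0756. The highest values mostly came without Y30F-DEX replicate 1, after which that group lies on slide 2 alone. The gene lists and transfected transcripts were not run, since the files pair no names with IDs. Dim features limit the data: 19 of 365 and 23 of 423 changed features had a group below background.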

Other observations

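The test with splits of the arrays was planned. Among the tests below, those of slide 2 as the origin of the negative correlation, of opposite responses, and of the slide 2 shift within groups were chosen only after the results were seen.

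For the difference of the effects the real labels gave 0 features. Every relabelling of treatment within each mutant gives at least that (100 of 100 drawn), so the count of relabellings decides nothing about chance. The highest other count was 755, from exchanging dexamethasone and DMSO in Y30E alone, which tests the sum of the 2 effects and adds nothing to the counts already given. For the effects themselves 10 splits of 6 arrays are too few for a share under 0.05. The real split gave 365 features in Y30F (highest other 3) and 423 in Y30E (highest other 2), each more than any other, so 1 of the 10 splits was as large. Between the mutants it gave 2 under DMSO (highest other 0) and 3 under dexamethasone (highest other 0), again 1 of 10. Features were filtered on the real groups, which can favour the real split. With the filter on all 12 arrays both counts between mutants were 0.

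Over all features the dexamethasone effects of the mutants correlated negatively, while most changed features moved the same way in both. An opposite response of the mutants as the general pattern is argued against by r = 0.307 without slide 2. An offset of slide 2, which enters the Y30F and Y30E effects with opposite sign, may account for the negative value, given the same r = 0.307. The negative r lay among dim features, at -0.320 in the dimmest 6679, while r was 0.648 in the brightest 6679 features. Without slide 2 the dimmest 6679 had r = 0.232, so nearness to background alone did not give a negative value. Opposite responses of single dim features stay open.

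Slide 2 stood apart from slides 1 and 3. After quantile normalization 98.7% of the first component's variance still lay between slides. That value gives neither which slide the component parts nor how much variance it then held. Quantile normalization gives every array the same distribution, so array scaling alone is argued against as the source of the separation between slides on that component. For slide 2 in particular, and for the size of its offset, array scaling stays open. Mutant or treatment is argued against. The shift of slide 2 within Y30F-DEX and the shift within Y30E-DMSO, which use different arrays, correlated with r = 0.473 over all features. A shift of features near background is a candidate explanation, with r = 0.502 in the dimmest 6679 features and -0.183 in the brightest 6679, though r was still 0.378 in the middle 6679. Whether hybridisation or RNA prepared together for slide 2 was the origin was not tested.

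With slide as a block, 18 features passed the test of the difference of the effects, 17 of them with a lower effect in Y30E. All of them (100%) were among the dimmest 6679 features, so instability near background may account for them. In 4 of them a group had no array well above background, and 2 passed without slide 2. A difference between the receptors in a few dim transcripts stays open, because each blocked effect rests on a single Y30F-DEX or Y30E-DMSO array.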
